A study of Homo sapiens with 4 samples.

How the data were processed

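ATAC-seq peak lists of 4 libraries of 786-O cells were used, 2 treated with DMSO and 2 with 5 µM ACSS2i for 24 h, grouped by the treatment given in the labels. Nothing in the labels says that replicates came from separate cultures, so p-values across libraries measure only the spread between these samples, which may be technical. Per the labels' protocols, frozen cells were thawed and treated with DNase I, nuclei were exposed to Tn5 for 30 min, and libraries were read as pairs of 150 bases.

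The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.38, Bowtie2, SAMtools 1.9, Picard 2.18.26, MACS2 2.1.2, DiffBind, deepTools 3.5.0 and bedtools, and the build hg38. The caller's options, any shift for the Tn5 insertion site and the treatment of duplicates and mitochondrial reads are not given in the sources used here. The deposited lists hold peaks called separately per library, with several summits possible within a peak. The score column deposited by the authors was a rescaled q-value and was not used beyond checking it. The fold column deposited by the authors is the enrichment ratio of the summit over local background within the library. The deposited −log10 p and −log10 q columns give the p-value and q-value of the peak caller within each library, and every deposited −log10 q was at least 2. The authors also deposited the offset of the summit in bp, which was checked to lie within its peak. The lists are described as filtered, and the filter is not given in the sources used here: the peak numbering lacked 11, 12, 16 and 15 numbers in the lists of DMSO replicates 1 and 2 and ACSS2i replicates 1 and 2. Fold and q are the authors' values per peak and were used only to describe or rank peaks within a list.

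The lists held 46692, 69876, 20514 and 29244 summits in the same order. Summits sharing an interval were counted as 1 peak that took the values of its strongest summit. Overlapping peaks of the 4 libraries (1 bp or more) were merged into regions, and a region was present in a library with a peak in it. Strength was the percentile of −log10 q within a library, and the strength of a gene or region in a group was the lower of its library percentiles. Read totals and fragment totals are not given in the sources used here. The fold and −log10 p columns were solved for a whole-number pileup and a Poisson background, which matched the deposited −log10 p within 0.001 for at least 99.99% of summits in each library, and the lowest background level was taken as the genome background coverage. That level scales with sequencing depth only where the caller extended fragments alike in every library. Binomial intervals are exact (Clopper-Pearson), and these and the limits for a count of 0 (3 counts) cover counting error only. The limits for a count of 0 are rough for short lists, and a list counted in full is not a sample of other genes.

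Gene positions came from a RefSeq table of GRCh38.p14, the same build, which gives the span of each gene. Strand, exons and genome sequence were not used here, so the promoter of the planned design was replaced by either end of a protein-coding gene span: a gene-end peak lies within 1000 bp of an end. Such a peak can belong to a neighbouring gene or to the 3′ end. Regions were classed as near a gene end, inside a gene span or between spans, and exon and intron classes and the planned motif comparison were not run.

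Library values were compared by two-sided exact permutation, for which 2 against 2 libraries allow no p below 0.333. Regions and genes present in both libraries of a group and neither of the other were counted, and regions also for the other 2 ways of pairing the libraries. Each of 20 gene lists (398 entries, all matched to the table, 1 through a synonym) was compared with 10000 random lists of the same size, drawn from the genes with a gene-end peak in both DMSO libraries and matched on deciles of DMSO strength. The resulting permutation p-values were adjusted by Benjamini-Hochberg over the 20 lists and describe these libraries. The lists cover the study genes, HIF targets, acetyl-CoA supply and histone acetylation, sterol and fatty acid synthesis, autophagy and lysosome, mitochondrial dynamics, HIF alpha turnover, glycolysis, kidney tubule, mesenchymal and matrix genes, AP-1 and immediate early genes, stress response, p53 targets, cell cycle, NF-kB, interferon response, constitutive genes and markers of immune, endothelial or stromal, and neuronal or muscle cells. Simulated lists of 20 genes among the 10471 genes with a DMSO peak were recovered at p under 0.05 in 1 of 10 cases when the odds of loss were multiplied by 2, in 6 of 10 when multiplied by 4 and in 6 of 10 when multiplied by 8, and 3, 5 and 8 of 200 unchanged lists passed.

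Genes were named by a rule: the 6 study genes; from each list up to 4 lost or gained members by strength, or else the 2 members with the strongest DMSO peak; the 10 strongest genes present in one group alone; and the 5 strongest regions away from gene ends in each direction. KAT6A, HDAC8, PFKFB3, CTSB, ATG7 and LAMP1 lie outside that rule and were named after their values were seen. Some genes of the lists are not reported here by name. Groups, gene lists, tests, the naming rule and most alternatives were fixed before the data were examined. Those alternatives were a reciprocal overlap of 50%, a −log10 q of at least 5, the 16400 strongest peaks of each library, a 500 bp window, unmatched random lists, a block by replicate number, and each library left out. Matching gene-end loss on strength and leaving out the libraries with the fewest and the most peaks together were added after seeing the data, as were the gene lists with each library left out. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 was used.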

Results

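Accessible chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 786-O cells, a clear cell renal cell carcinoma line that lacks functional VHL. Cells received DMSO as the vehicle or 5 µM ACSS2i, named in the labels as the compound directed at ACSS2, for 24 h. There were 2 libraries per group, 4 in all, and each library has its own list of peaks on hg38. The series concerns ACSS2, which makes acetyl-CoA from acetate, the hypoxia factor HIF-2α (encoded by EPAS1) and the E3 ubiquitin ligase MUL1, and this experiment asked which accessible regions differ after ACSS2i. Read totals were not given in the sources used here. The background coverage recovered from the peak values was 2.06 and 1.75 fragments per position in DMSO replicates 1 and 2 and 2.32 and 3.16 in ACSS2i replicates 1 and 2.

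Far fewer genes had an accessible end in the ACSS2i lists than in the DMSO lists. A peak within 1000 bp of an end of the gene was present for 10545 and 12013 of 20037 protein-coding genes in the DMSO libraries and for 6519 and 8161 in the ACSS2i libraries. Of the 10471 genes with such a peak in both DMSO libraries, 6075 had one in all 4 libraries, and 1979 (18.9%) had none in either ACSS2i library. These 1979 genes included the HIF targets IGFBP3, PLIN2 and LOX, the acetyltransferase genes CREBBP and KAT6A, the autophagy gene BECN1 and the glycolytic gene GPI, and are called lost here. In the full lists no gene showed the opposite pattern: of the 7950 genes with no DMSO peak, 0 had a peak in both ACSS2i libraries, which allows a share of up to 0.0377%, and 6 had one in a single ACSS2i library. The count of lost genes was 3424 without DMSO replicate 1 and 3986 without ACSS2i replicate 2, and it was 331 when each list was reduced to its 16400 strongest peaks. Of these 331, 188 were also among the 1979 lost in the full lists, so the 331 are not a subset of the 1979. Cutting the lists to 1 length also removes any general difference in the number of peaks. Of the lost genes named above, only GPI was among the 331, while the 10 strongest lost genes, named further below, all were. The count in the opposite direction, 0 with all libraries and peaks, was 98 at that equal length, 7 without DMSO replicate 2, 5 without ACSS2i replicate 1, 1 without ACSS2i replicate 2, and 78 without both the shortest and the longest list.

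None of the 5 study genes with a peak in both DMSO libraries was lost in the full lists, which allows a share of up to 60%. Means of matched random lists follow in brackets. At the stricter threshold 3 of 5 were lost (2.49), and without ACSS2i replicate 2 also 3 of 5 (2.38). With a 500 bp window 1 of 5 was lost (1.28), at equal list length 1 of 2 (0.143), and without DMSO replicate 1, 1 of 6 (0.743). The gene lost without DMSO replicate 1 was ACSS2, whose peak lay at the edge of the window, as described below. MUL1 (chromosome 1, 20499448 to 20508151) had a peak at its upper end in all 4 libraries, with fold enrichments of 5.02 and 8.66 in DMSO and 3.26 and 3.14 in ACSS2i. Its −log10 q was 8.23 and 26.6 in DMSO and 2.21 and 2.88 in ACSS2i, and both ACSS2i values lay near the lower limit of the lists, which is 2. EPAS1 (chromosome 2, 46297407 to 46386697) had a peak at its lower end in both DMSO libraries, with folds of 5.03 and 7.23, and in ACSS2i replicate 2, with a fold of 3.02, but none in ACSS2i replicate 1. With lists of equal length, the EPAS1 peak ranked among the 16400 strongest in both DMSO libraries, and its peak in ACSS2i replicate 2 was called but ranked below them, whereas ACSS2, MUL1, HIF1A and VHL had mixed patterns and ARNT kept a peak in all 4.

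HIF1A (chromosome 14, 61695513 to 61748258), which encodes the other main HIF alpha subunit, and VHL (chromosome 3, 10141778 to 10153667), whose product marks HIF alpha subunits for degradation, had the same pattern as EPAS1. Their folds were 4.87 and 11.7 in DMSO and 4.08 in ACSS2i replicate 2 for HIF1A, and 5.61, 10.0 and 4.75 for VHL. ARNT (chromosome 1, 150809713 to 150876599), the shared HIF beta subunit, had peaks in all 4 libraries, with folds of 10.0, 11.8, 4.88 and 7.03. ACSS2 itself (chromosome 20, 34874989 to 34927959) had a gene-end peak in DMSO replicate 2 alone, with a fold of 7.25. Its counted pattern thus differed within the DMSO group. That peak (34875935 to 34876860) lay inside the gene, and only its edge fell within the window around the lower end. A slightly narrower peak at the same site in another library would not have been counted. Whether the other libraries had such a peak was not examined. Folds are the authors' own values, each set against the background of its own library, and no test between groups was run on them.

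HIF target genes kept most of their gene-end peaks. Of 24 HIF targets with a peak in both DMSO libraries, 15 had one in all 4 libraries and 5 were lost: IGFBP3, which encodes a binding protein for insulin-like growth factors, PLIN2, which coats lipid droplets, LOX, which crosslinks collagen, STC2, a secreted glycoprotein, and PFKFB3, a regulator of glycolysis. Random lists of the same size and DMSO peak strength lost 4.29 on average, which put the HIF targets at percentile 68.2 (permutation p = 0.863, adjusted p = 1.00). The IGFBP3 peak was the strongest of the 5 in DMSO, at −log10 q of 9.49 and 18.7, and the STC2 peak was among the weakest, at 2.87 and 10.2. Without ACSS2i replicate 2, 9 of 24 HIF targets were lost (random mean 8.17). At equal list length 1 of 16 was lost (random mean 0.678), namely AXL, which was not lost in the full lists. Among 18 genes of HIF alpha turnover, 3 were lost, namely the ubiquitin ligase STUB1, the elongin subunit ELOB and the prolyl hydroxylase EGLN2, against a random mean of 3.97, and 8 of 18 were lost without ACSS2i replicate 2 (random mean 7.64). Of 15 glycolysis genes, 4 were lost (GPI, SLC2A3, HK2 and PFKL), against a random mean of 3.42.

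Genes that supply acetyl-CoA or that write, remove and read histone acetylation lost 6 of 21 gene-end peaks. These included KAT2A, CREBBP and KAT6A, which encode acetyltransferases, the deacetylase HDAC8, and ACSS1, the mitochondrial relative of ACSS2. Random lists lost 4.53 on average, and the list lay at percentile 82.4 (permutation p = 0.511, adjusted p = 1.00). Without ACSS2i replicate 2 the list lost 10 of 21 (random mean 8.35), and at equal list length 0 of 13 (random mean 0.613). The CREBBP peak had folds of 4.76 and 8.02 in the DMSO libraries. The KAT2A peaks of the DMSO libraries lay at opposite ends of the gene, so they were not the same peak. In the sterol and fatty acid list, 1 of 19 genes was lost, SREBF1, which encodes a master regulator of lipid synthesis, against a random mean of 2.86. This list lost 2 of 19 without ACSS2i replicate 1 (random mean 3.465) and 3 of 19 without ACSS2i replicate 2 (random mean 6.04).

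With all libraries and peaks, the list at the highest percentile of its random lists was autophagy and lysosome, with 7 of 19 genes lost against a random mean of 3.41 (percentile 99.1, permutation p = 0.0302, adjusted p = 0.448). Its lost members were BECN1 and ATG7, which act in forming autophagosomes, the lysosomal membrane genes LAMP1, LAMP2 and MCOLN1, and the lysosomal enzyme genes HEXA and CTSB. BECN1 had DMSO folds of 6.38 and 9.07 and HEXA 6.06 and 7.99. The peak counted for MCOLN1 lay outside its gene span, past its upper end, and can belong to a neighbouring gene. At the other extreme, 1 of 19 AP-1 and immediate early genes was lost, EGR3, against a random mean of 4.19 (percentile 1.23, permutation p = 0.0448, adjusted p = 0.448). Autophagy and lysosome genes lost 0 of 10 at equal list length and 6 of 17 at the stricter threshold (percentile 75.2), and 11 of 23 without DMSO replicate 1 and 8 of 19 without ACSS2i replicate 2 (percentile 68.3). The AP-1 list lost 2 of 20 without DMSO replicate 2, 2 of 19 without ACSS2i replicate 1 and 4 of 19 without ACSS2i replicate 2. The permutation p of the autophagy and lysosome list was 0.100 with unmatched random lists, 0.0702 without DMSO replicate 1, 0.116 without ACSS2i replicate 1 and 0.153 without both the shortest and the longest list. That of the AP-1 list was 0.0308 without DMSO replicate 1, 0.0372 without ACSS2i replicate 2, 0.223 with a 500 bp window, 0.388 at the stricter threshold, 1.00 at equal length, 0.198 unmatched, 0.119 without DMSO replicate 2, 0.0882 without ACSS2i replicate 1 and 0.186 without both of those lists. With random lists matched on the strength deciles of both DMSO libraries, the permutation p was 0.0554 for autophagy and lysosome and 0.0296 for AP-1. The EGR3 peak lay at the lower limit of DMSO replicate 1, at −log10 q of 2.03. Neither list passed the correction over the 20 lists fixed before the data were examined, so 0 of 20 passed and 2 had an unadjusted p under 0.05.

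None of the remaining lists had an unadjusted permutation p under 0.05, and every adjusted p was 1.00. Cell cycle genes lost 1 of 22 (BUB1, a spindle checkpoint kinase), stress response genes 1 of 18 (ATF6, a sensor of unfolded protein), p53 targets 1 of 12 (ZMAT3) and mitochondrial dynamics genes 2 of 15 (FUNDC1 and PINK1, which act in mitophagy). NF-kB and inflammatory genes lost 2 of 14, the neighbouring chemokine genes CXCL8 and CXCL1, and interferon response genes lost 3 of 14, IRF7, OAS3 and IFIT2. Mesenchymal and matrix genes lost 4 of 16, namely ITGA5, ZEB2 and the adjacent collagen genes COL4A1 and COL4A2, which share a single peak. Constitutive genes lost 4 of 24, HPRT1, UBB, EEF2 and PSMB4, against a random mean of 4.02 (percentile 50.9). The EEF2 peaks of the DMSO libraries did not overlap, and that of DMSO replicate 2 lay outside the gene span, so they were not the same peak. Kidney tubule genes lost 0 of 7, which allows a share of up to 42.9%; KRT8 and KRT18, which encode epithelial keratins and share a peak, had it in all 4 libraries. Several of these counts depended on single libraries. Without ACSS2i replicate 2, the matched random lists also lost more, and their means follow in brackets. Cell cycle genes then lost 6 of 22 (5.21), mitochondrial dynamics genes 4 of 15 (4.81) and interferon response genes 6 of 14 (7.01). Constitutive genes lost 7 of 24 (9.06), p53 targets 2 of 12 (4.77) and kidney tubule genes 2 of 7 (3.06). Without DMSO replicate 1, cell cycle genes lost 3 of 24 (3.15), stress response genes 2 of 19 (3.23), p53 targets 2 of 13 (3.19) and kidney tubule genes 1 of 8 (2.87). Without ACSS2i replicate 1, stress response genes lost 3 of 18 (1.80) and p53 targets 2 of 12 (2.70). Other settings also moved some counts. NF-kB and inflammatory genes lost 4 of 13 with a 500 bp window (2.37) and 5 of 14 at the stricter threshold (4.48). At that threshold p53 targets lost 4 of 12 (4.35) and stress response genes 3 of 18 (3.24).

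Most markers of other cell types had no gene-end peak in any library. Immune markers had gene-end peaks for 2 and 4 of 16 genes in the DMSO libraries and for 2 in each ACSS2i library, and CD68 and CSF1R were those present in all 4. Endothelial and stromal markers had peaks for 3 and 4 of 15 genes in DMSO and for 2 in each ACSS2i library, with PDGFRB lost. The peaks counted for PDGFRB lay outside its gene span. They lay inside the span of CSF1R, within 1000 bp of the upper end of CSF1R, so they can belong to that gene. CSF1R itself was counted as present through peaks at its lower end. Neuronal and muscle genes had peaks for 2 of 18 in each DMSO library and for 0 and 1 in ACSS2i, with SNAP25 lost. Without DMSO replicate 1, 2 of 4 immune (random mean 2.02) and 2 of 4 endothelial and stromal markers (1.76) were lost. Without ACSS2i replicate 2, 2 of 2 neuronal and muscle genes were lost (1.28).

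**Figure D1:**
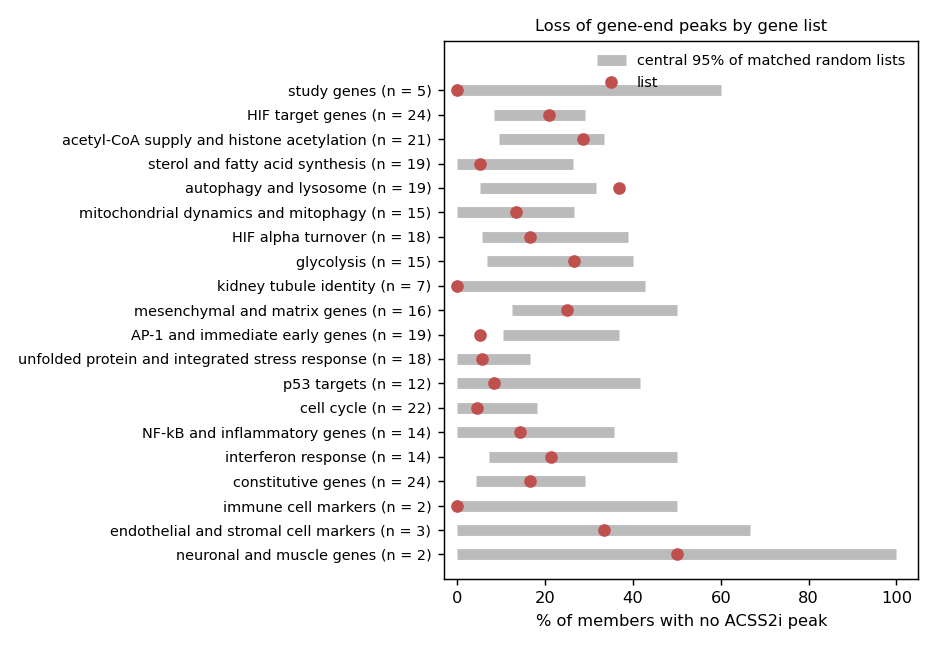
Loss of gene-end peaks in each of 20 gene lists. The horizontal axis is the percentage of members with a peak in both DMSO libraries that had none in either ACSS2i library, points are the lists, bars are the central 95% of 10000 random lists matched on DMSO peak strength, and n is the number of members with a peak in both DMSO libraries. The autophagy and lysosome list (7 of 19) lies above its bar and the AP-1 list (1 of 19) below its bar, and neither passed the correction over lists.

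The strongest gene-end peaks that were absent from both ACSS2i libraries were those at SLC75A1, TIGD5, SNTB1, TTPAL, SRRD, ZBTB46, OVOL3, ZCCHC14, ESPNL and LPCAT1. All 10 genes were also only in DMSO at equal list length. The SLC75A1 peak (gene at chromosome 4, 2930567 to 2934825) had folds of 6.81 and 8.02 and lay at percentile 97.1 of strength in the DMSO library where it ranked lower. TIGD5 (chromosome 8, 143597831 to 143603224), from a family of transposase-derived genes, had folds of 8.22 and 7.79, and SNTB1 (chromosome 8, 120535756 to 120812046), which encodes a syntrophin, had 7.40 and 7.85. LPCAT1 (chromosome 5, 1461427 to 1523960), an enzyme of phosphatidylcholine remodelling, had 6.09 and 6.53. The ZCCHC14 peaks lay at opposite ends of that gene in the DMSO libraries. The peaks counted for SLC75A1, TIGD5, TTPAL, ZBTB46, OVOL3 and ESPNL lay just outside those gene spans, so they can belong to neighbouring genes.

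Away from gene ends, the 5 strongest regions of both DMSO libraries with no ACSS2i peak were on chromosomes 15, 7, 5, 10 and 17. The region on chromosome 15 (64232174 to 64233124, nearest gene CSNK1G1) had folds of 9.63 and 14.7, and that on chromosome 7 (126701043 to 126701601, nearest gene GRM8) had 8.64 and 12.8. The region on chromosome 5 (177370526 to 177371092) lay 1.79 kb from an end of RGS14 and that on chromosome 10 (21285321 to 21286309) 7.24 kb from an end of NEBL. These 4 lay inside gene spans, while the region on chromosome 17 (81329051 to 81329955, nearest gene SLC38A10) lay between gene spans.

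The DMSO lists held 34696 and 50294 peaks and the ACSS2i lists 16400 and 22044, which is 42495 ± 11029.5 against 19222 ± 3990.9 peaks (SD, n = 2 per group), a ratio of 0.452. Both ACSS2i values lay below both DMSO values (two-sided exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). Peaks covered 23.7 and 34.5 Mb in DMSO and 8.27 and 12.9 Mb in ACSS2i, and the median peak width was 565 and 558 bp against 414 and 476 bp. In the 13306 regions present in all 4 libraries, the median summit pileup was 19.4 and 44.1 times the genome background in the DMSO libraries and 8.64 and 9.17 times in the ACSS2i libraries. The DMSO mean was 3.57 times the ACSS2i mean, the DMSO libraries differed from each other by a factor of 2.27, and DMSO replicate 1, the nearer to ACSS2i, exceeded the ACSS2i mean by a factor of 2.2. The exact permutation p of this signal measure was 0.333.

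**Figure D2:**
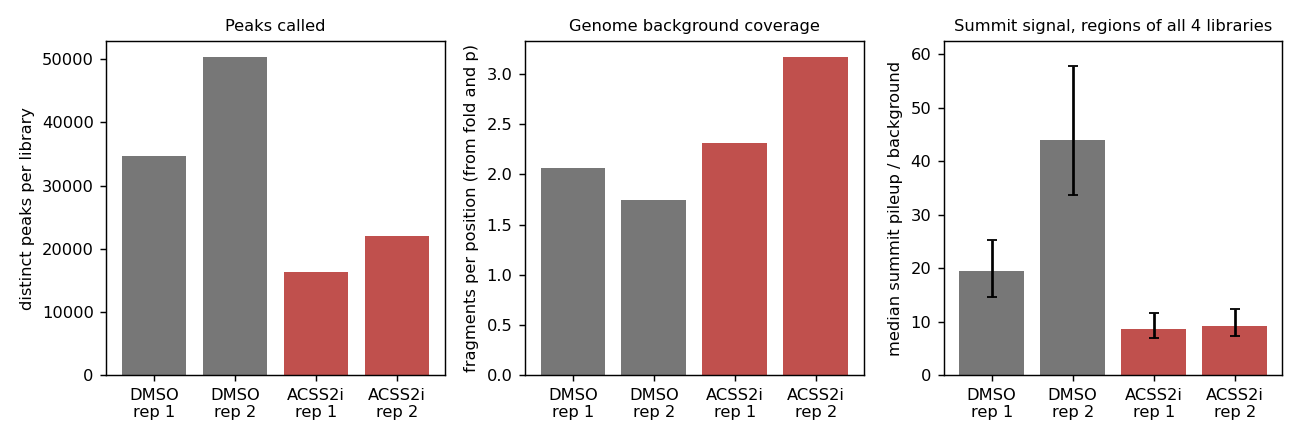
Peaks called, genome background coverage and summit signal of the 4 libraries, DMSO in grey and ACSS2i in red. Bars are single libraries, and the error bars of the right panel span the quartiles over the 13306 regions present in all 4. ACSS2i libraries had fewer peaks (16400 and 22044), higher background coverage (2.32 and 3.16) and lower summit signal over background (8.64 and 9.17).

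Merging all peaks gave 53572 regions, of which 31506 had a peak in both DMSO libraries and 13306 in all 4. Of 13381 regions with a peak in both ACSS2i libraries, 13369 (99.9%) had one in at least 1 DMSO library. Of the 23465 regions with a peak in any ACSS2i library, 1400 (5.97%) had none in either DMSO library. In the opposite direction, 10556 regions, 33.5% of those in both DMSO libraries, had no ACSS2i peak, and 12 regions were present in both ACSS2i libraries alone. The count of 10556 was 28042 without DMSO replicate 1 and 16460 without ACSS2i replicate 2, and the count of 12 was 75 without DMSO replicate 2, 1151 without ACSS2i replicate 1, 264 without ACSS2i replicate 2 and 2157 without both the shortest and the longest list. Replicate lists also differed in length: 92.9% of the peaks of DMSO replicate 1 overlapped a peak of DMSO replicate 2, and 63.7% the other way. For ACSS2i these shares were 84.1% and 61.3%.

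Dividing the 4 libraries by treatment left 10568 regions found in both libraries of 1 pair and neither of the other, against 819 and 233 for the other pairings of the libraries. With the 16400 strongest peaks of each library, the treatment split gave 1337 regions, 835 in DMSO and 502 in ACSS2i, and the split that set the replicates numbered 1 against those numbered 2 gave 1444. The remaining split gave 942. At equal length 79.7% of the peaks of DMSO replicate 1 overlapped DMSO replicate 2 and 76.1% of those of ACSS2i replicate 1 overlapped ACSS2i replicate 2, while shares between groups ran from 73.6% to 79.7%. By the Jaccard index of base pairs the libraries shared 0.562 within DMSO and 0.489 within ACSS2i, against 0.373 to 0.520 between groups. The treatment split was thus larger than 1 of the other splits and smaller than the other. Lists cut to equal length by rank cannot show a general drop in signal. The splits at equal length therefore compare only which peaks ranked highest, and do not decide whether treatment lowered the signal.

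**Figure D3:**
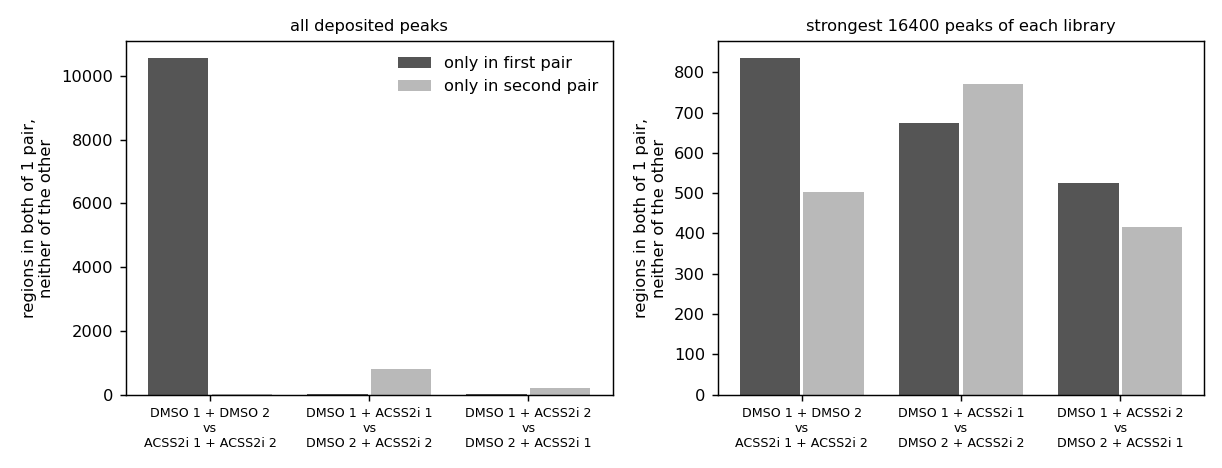
Regions with a peak in both libraries of 1 pair and neither of the other pair, for the 3 ways of dividing the 4 libraries into pairs. The left panel uses all deposited peaks and the right panel the strongest 16400 of each library, with separate vertical scales. The treatment split stands apart with all peaks (10556 and 12) and not at equal list length (835 and 502, against 673 and 771 for replicates numbered 1 against those numbered 2). Lists of equal length cannot show a general drop in signal.

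Regions without an ACSS2i peak were mostly weak ones in DMSO. Their median strength percentile was 27.9 in DMSO replicate 1 and 44.1 in DMSO replicate 2, against 79.1 and 85.4 for regions present in all 4. Loss ran from 82.0% of regions in the lowest decile of DMSO strength to 0.0635% in the highest. Regions near gene ends, the group that contains the peaks of MUL1 and ARNT, were lost less often than others: 1943 of 9399 (20.7%) against 8613 of 22107 (39.0%). Gene-end regions made up 18.4% of the regions lost and 39.4% of those in all 4 (Fisher's exact test, odds ratio 0.347, p = 5.01e-278), a test that compares the regions of these libraries and not the conditions. Among all regions of both DMSO libraries the odds ratio of loss near gene ends was 0.408 (95% interval 0.386 to 0.432). After matching on the strength deciles of both DMSO libraries, an adjustment chosen after seeing the data, it was 0.806 (95% interval 0.747 to 0.869).

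**Figure D4:**
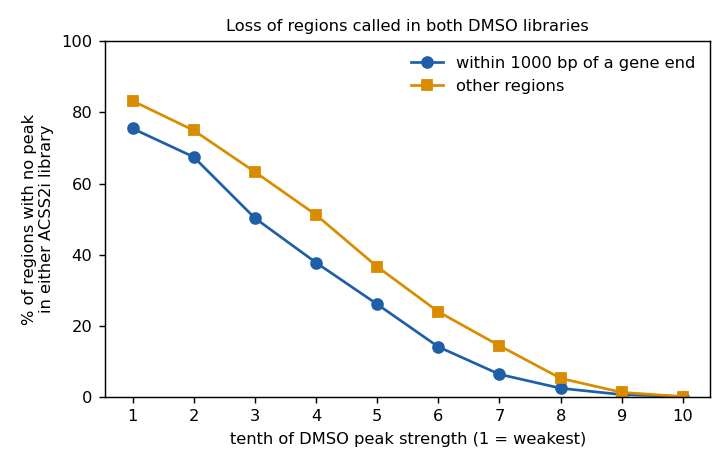
Percentage of regions of both DMSO libraries with no peak in either ACSS2i library (vertical axis), by decile of DMSO peak strength (horizontal axis, 1 the weakest), for regions within 1000 bp of a gene end (circles) and other regions (squares). Over all regions loss ran from 82.0% in the weakest decile to 0.0635% in the strongest.

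The share of peaks near gene ends was 28.1% (95% exact binomial interval 27.6 to 28.6) and 22.6% (22.2 to 22.98) in the DMSO libraries and 35.2% (34.4 to 35.9) and 32.9% (32.3 to 33.6) in the ACSS2i libraries. Both ACSS2i values were the higher ones (exact permutation p = 0.333, n = 2 per group). Among the 16400 strongest peaks of each library the shares were 35.6% and 40.3% in DMSO and 35.2% and 35.9% in ACSS2i, so the ACSS2i shares were no longer both above the DMSO shares.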

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

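The tests of coverage, of the constitutive genes and of peak strength near gene ends were chosen only after the results were seen. Background coverage drew attention because it lay outside the measures compared by the study: it was 1.44 times as high in ACSS2i as in DMSO libraries on average, with both ACSS2i values (2.32 and 3.16) above both DMSO values (2.06 and 1.75).

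The first pattern was the smaller number of gene-end peaks and regions in ACSS2i, including those of EPAS1 and HIF1A in 1 of 2 libraries. Lower sequencing coverage would need a background ratio under 1, and it was 1.44, which argues against it if fragments were extended alike in every library. Whether constitutive genes were spared stays open: their list, with HPRT1, UBB, EEF2 and PSMB4 lost, lay at percentile 50.9 of matched random lists, but at 3.18 without DMSO replicate 1, 5.05 at the stricter threshold and 14.9 without ACSS2i replicate 2, and the 95% exact binomial interval of its loss (4.74% to 37.4%) spans the random mean of 16.8%. A uniform drop in signal over background may account for most of the pattern: a single scale factor per ACSS2i library (0.261 and 0.268) predicted 7548 lost regions against 10556 observed, a ratio of 0.715, inside the bound of 1.5 times set before the result was seen but short of the observed count. For single libraries, the model predicted 12719.5 regions absent from ACSS2i replicate 1 against 16453 observed. For ACSS2i replicate 2 it predicted 9747 against 12303. From DMSO replicate 2 it predicted 18333 regions absent from DMSO replicate 1 against 18228 observed, a ratio of 1.01. The shortfall in ACSS2i thus stays open, as does whether such a drop came from ACSS2i or from the efficiency of the libraries.

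The second pattern was the lower loss near gene ends, the places where MUL1 and ARNT kept their peaks. Among the regions of both DMSO libraries, matching on strength moved the odds ratio of loss from 0.408 to 0.806 (95% interval 0.747 to 0.869), and the interval excluded 1. Deciles of strength thus did not account for the whole difference. The odds ratio was 0.573 with a single set of deciles, and it moved further towards 1 with deciles of both DMSO libraries. Differences in strength within deciles may remain, so the test cannot exclude strength as the explanation. The width of the regions and a biological difference between gene ends and other regions were not tested.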

How the results depend on the processing

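Chosen after seeing the data were the matching of gene-end loss on strength (odds ratios 0.573 and 0.806, from 0.408 unmatched), the gene lists with each library left out, and leaving out the libraries with the fewest and the most peaks, which gave 15285 regions and 2462 genes only in DMSO and 2157 regions only in ACSS2i. At equal list length 835 regions and 331 genes were only in DMSO and 502 regions only in ACSS2i, and replicate overlap was 79.7% (DMSO) and 76.1% (ACSS2i). A reciprocal overlap of 50% gave 1017 regions only in ACSS2i, 8858 in all 4, and replicate overlaps of 74.5% and 61.5%. The stricter threshold gave 6 regions only in ACSS2i and 8708 in all 4. The cause of these shifts was not tested, apart from the shorter lists themselves.

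Leaving out each library in turn gave 12304 to 28042 regions only in DMSO, 16 to 1151 only in ACSS2i, 2050 to 3986 genes only in DMSO and peak ratios of 0.382 to 0.554; a group of 1 library sets a weaker condition, and these are values with no test. The labels do not say whether libraries of the same replicate number were handled together. Same-numbered libraries deviated with correlations of -0.0873 over presence and 0.0933 over strength. At equal length, however, the split by replicate number was the largest, at 1444 regions against 1337 and 942. The replicate block gave an exact sign-flip p of 0.5 for peaks per library, the smallest that 2 pairs allow. No gene list passed with a 500 bp window, equal length, the stricter threshold, unmatched lists, or each library left out, and gene-end regions stayed under-represented among lost regions in every setting run for them. Reciprocal overlap gives no value by gene, and the motif comparison with its alternatives was not run. Unknown read depth limits every absent peak to "not called".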

Other observations

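The gene families and chromosomes below, the genes named at equal length and the test of the filter were chosen only after seeing the data, and the test across chromosomes was set before its result was seen. Of 49 EIF genes, which encode translation initiation factors, 34 had a gene-end peak in all 4 libraries and 1 was lost, against 5.67 in matched random lists (percentile 0.385, permutation p = 0.0146, adjusted p = 0.307 over 21 families). Vacuolar ATPase subunits, which acidify lysosomes, lost 5 of 19 against 1.72 (percentile 99.0), and keratin genes lost 2 of 5 against 0.289 (percentile 98.8). Mitochondrial ribosomal protein genes lost 20 of 68 against 15.0, complex I genes 13 of 42 against 9.03, and proteasome genes 11 of 44 against 7.65. None of the 21 families passed the correction. Zinc finger genes of the ZNF family lost 83 of 355, against 76.8.

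With lists of equal length, 331 genes had a gene-end peak among the strongest of both DMSO libraries and neither ACSS2i library, and 98 the reverse. Of the fixed lists, EPAS1, AXL and GPI were among the former. The latter included DHCR7, of cholesterol synthesis, BRD2, PKM and DUSP5. The genes highest in rank on that side were HEBP1, TMEM259 and SBF2.

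The share of regions lost on chromosome 14 was 46.4% against 41.4% expected at matched strength (odds ratio 1.39, 95% interval 1.16 to 1.68). It was the only one of 24 chromosomes to pass the Cochran-Mantel-Haenszel test after Benjamini-Hochberg adjustment. That test takes regions of these libraries as its units and does not compare the conditions. On the X chromosome 47.5% of regions were lost (odds ratio 1.21), which did not pass.

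A further pattern was the 1400 regions, 5.97% of those in any ACSS2i library, that had no DMSO peak. Most came from a single library: 1138 had a peak in ACSS2i replicate 2 alone, 250 in ACSS2i replicate 1 alone and 12 in both. They were weak, with median folds of 3.52 in ACSS2i replicate 1 and 3.21 in replicate 2. They were rarely near gene ends (4.96% and 1.22%). On chromosome 8, which held 4.54% of the regions in both DMSO libraries, lay 208 of them (14.9%). That share was not separated by library. Of the 12 present in both ACSS2i libraries, the strongest away from gene ends lay on chromosome 6 (61322949 to 61323134, folds 32.6 and 30.2), chromosome 1 (143214651 to 143214872, folds 22.01 and 16.3, and 123755564 to 123755820, folds 11.2 and 10.3), chromosome 21 (8420428 to 8420606, folds 9.65 and 13.2) and chromosome Y (11531546 to 11531736). These regions lay 220 to 2293 kb from the nearest gene end. The 12 had a median width of 265.5 bp, against 1117 bp for regions in all 4 libraries. Genome sequence was not used, so whether they lie in repeated sequence was not examined. Removal of such peaks from the DMSO lists by the authors' filter could account for few of them, since 1 of the 12 lay at a gap in the peak numbering of both DMSO lists. Uneven background DNA between chromosomes may contribute, but across 24 chromosomes the DMSO local background and the rate of these regions had a Spearman's rho of 0.183 (permutation p = 0.391) and a Pearson's r of 0.259 (permutation p = 0.218; 0.279 without the 2 chromosomes farthest from the median), which decides nothing; an effect of ACSS2i on these regions was not tested.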
